A study of Mus musculus with 48 samples.

How the data were processed

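The series holds 48 bulk RNA-seq samples of mouse lymph node, spleen, bone marrow and sorted tumour cells, made per the labels' protocols with the TruSeq Stranded mRNA kit and sequenced as paired-end reads of 50 bp. Groups were taken from the sample titles. The submitters' processing notes name HISAT2, edgeR and the builds GRCm38 and mm10, without versions, roles or order. The counting program, its strand setting, the annotation release and the filter on low genes are not given in the sources used here.

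2 tables were read. The authors' deposited table of the tumour comparison holds, per the file headers, a log2 fold change and a mean log2 CPM per gene for CD45-negative tumour cells. The same deposited table holds an F statistic, a score with no fixed range, and a p-value with a p-value adjusted over the genes. Benjamini-Hochberg adjustment of the deposited p-values over the 11340 genes gave the deposited adjusted values to within 1.6e-14. Each deposited F and p together imply 74.15 denominator degrees of freedom for every gene checked, which left out genes with a low F. The libraries in the authors' fit are not stated, and the sign of the fold change is not stated either. Values of this table are printed without SD or n.

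From the deposited count table the gene identifiers, biotypes and coordinates were used. Its 48 per-sample columns are named by tissue and running number and match no single sample title, so they were not used in any step. The planned quasi-likelihood fits, the planned list tests on counts and the depth per library are therefore not analysed here, which leaves 1 of 8 planned comparisons, taken from the deposited table in place of an own fit. No own p-value per gene was computed, and whether the 12 tumour samples come from separate animals is as the titles number them.

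Gene symbols of the deposited table were matched to Ensembl identifiers, with a match for 11340 of 11340 genes, of which 13 symbols are shared by several identifiers. Strand and exons came from GENCODE release M21 on GRCm38, in which 99.42% of the identifiers of the count table have identical start and end, and 11320 genes received a strand. A gene was counted as having opposite-strand coding exons when its exons share at least 50 bases with those of a protein-coding gene on the other strand. Minimums of 1 and 200 bases were tried as well. The class and these alternatives were chosen after the data had been seen.

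Gene lists were tested with camera on preranked statistics (limma 3.58.1, R 4.3.3), using the signed square root of the deposited F, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists with at least 5 members. The other 23 of the 50 lists had fewer members. The test was also run on simulated normal statistics for the 11340 genes, drawn independently, with 6 lists shifted by 1 SD in 50 simulations. There 75% of shifted lists were recovered and 0.24% of unshifted lists were called, a rate that does not cover lists of correlated genes. An estimated correlation needs values per library and was not computed. Alternatives at correlations of 0.05 and 0, on ranks, on the log2 fold change, on genes with a mean log2 CPM of at least 4 and on genes without opposite-strand coding exons were tried, all chosen after the data had been seen. Call counts were recomputed at adjusted p below 0.01 and 0.1, with Bonferroni adjustment and on the same subsets of genes.

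Medians of gene sets were set against 10000 random sets, drawn for each member from the 50 genes nearest in mean log2 CPM, with 20 bins of mean log2 CPM as another way of matching. Values were also simulated independently for 7369 coding genes without opposite-strand coding exons. Of lists of 20 such genes, 97% of those shifted down by 1 SD and 2.5% of unshifted ones fell below the 2.5 percentile. These rates do not cover lists of correlated genes. Shares carry exact Clopper-Pearson intervals of 95%, which cover counting error only. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

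Named genes followed a rule fixed before the data were examined. The rule takes Qpctl and Qpct, the 10 called genes with the largest positive and the 10 with the largest negative fold change at a mean log2 CPM of at least 1, and the 4 members with the smallest p of each list called or described. Predicted and clone names and receptor or immunoglobulin segments are given as counts, and they made up 18 of the 37 positive and 0 of the 36 negative calls of the authors' deposited table. Genes named outside the rule, in the closing part, were chosen after their values were seen. Some genes that the rule takes are not reported here.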

Results

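RNA sequencing was carried out on 48 mouse samples in 10 groups to ask what loss of QPCTL changes in tumours and in lymphoid organs. QPCTL is the Golgi-resident glutaminyl cyclase, an enzyme that forms pyroglutamate at the amino terminus of secreted and membrane proteins. Whole lymph node, spleen and bone marrow were taken at baseline from mice aged 10 to 15 weeks, with 4 samples per organ and genotype. Lymph nodes and sorted tumour cells were taken 14 days after inoculation with B16F10 melanoma cells, with 6 samples per tissue and genotype. Host and tumour cells had the same genotype in every tumour sample, so knockout mice carried knockout tumours and wild-type littermates carried wild-type tumours. The tumour samples were live cells without surface CD45, a gate that keeps melanoma and stromal cells and removes leukocytes. The labels give paired-end reads of 50 bp and an average of 18 M reads per sample.

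The comparison described here is that of the knockout and wild-type CD45-negative tumour cells, which rests on the authors' deposited table of 11340 genes. The other 7 comparisons of the design, in lymph node, spleen and bone marrow, are not analysed here, because the count columns carry a tissue and a running number and no genotype. The source does not state which genotype was subtracted from which, so fold changes are given as positive or negative and not as higher or lower in the knockout. Host and tumour genotype cannot be separated in this comparison, because they always changed together.

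The targeted gene came first. Qpctl (ENSMUSG00000030407, chromosome 7, 19139702 to 19149291, minus strand, GRCm38) had a log2 fold change of 0.69 in the authors' deposited table, with p = 0.169 and an adjusted p of 0.494. Its level therefore did not settle the direction of the subtraction. Qpct, which encodes the secreted glutaminyl cyclase, was not among the genes of the authors' deposited table. Cd47, whose product is a known substrate of QPCTL, had a log2 fold change of -0.57 in the authors' deposited table. The adjusted p of Cd47 in the authors' deposited table was 0.682, at a low mean log2 CPM of 3.77. Its receptor gene Sirpa had -0.40 with an adjusted p of 0.542 in the authors' deposited table.

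At an adjusted p below 0.05, 73 genes were called in the authors' deposited table, 37 with a positive and 36 with a negative fold change. The positive calls held 19 protein-coding genes and 18 genes of non-coding classes, whereas 35 of the 36 negative calls in the authors' deposited table were protein-coding. Fold changes of the authors' deposited table leaned to the negative side, with 6639 of 11340 genes below 0 and a median of -0.14. Position relative to other genes went with the sign. Of the 37 positive calls of the authors' deposited table, 32 share at least 50 exonic bases with a protein-coding gene on the opposite strand, against 5 of the 36 negative calls (Fisher's exact test, two-sided, p = 2.23e-10 across genes, which are not independent replicates). Over all genes of the authors' deposited table, the 3379 with such an overlap had a median log2 fold change of 0.25 and the 7941 without it had -0.31. In the authors' deposited table, 559 of 582 genes with the overlap at a mean log2 CPM of at least 8 were positive (median 0.33). At that level, 58 of 88 genes without it in the authors' deposited table were negative (median -0.23). Genes with the overlap made up 48 of the 50 most abundant genes of the authors' deposited table, although the library kit keeps strand information. The mitochondrial gene mt-Nd6, which is encoded on the light strand, was called in the authors' deposited table (0.74, adjusted p = 0.017), with a mean log2 CPM 4.098 above the median of 6 heavy-strand coding genes. Of 771 antisense genes, 617 had a higher mean log2 CPM than their coding partner in the authors' deposited table. Whether the values of a gene or list named here count reads of its own transcripts or of the opposite strand is therefore not settled.

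**Figure D1:**
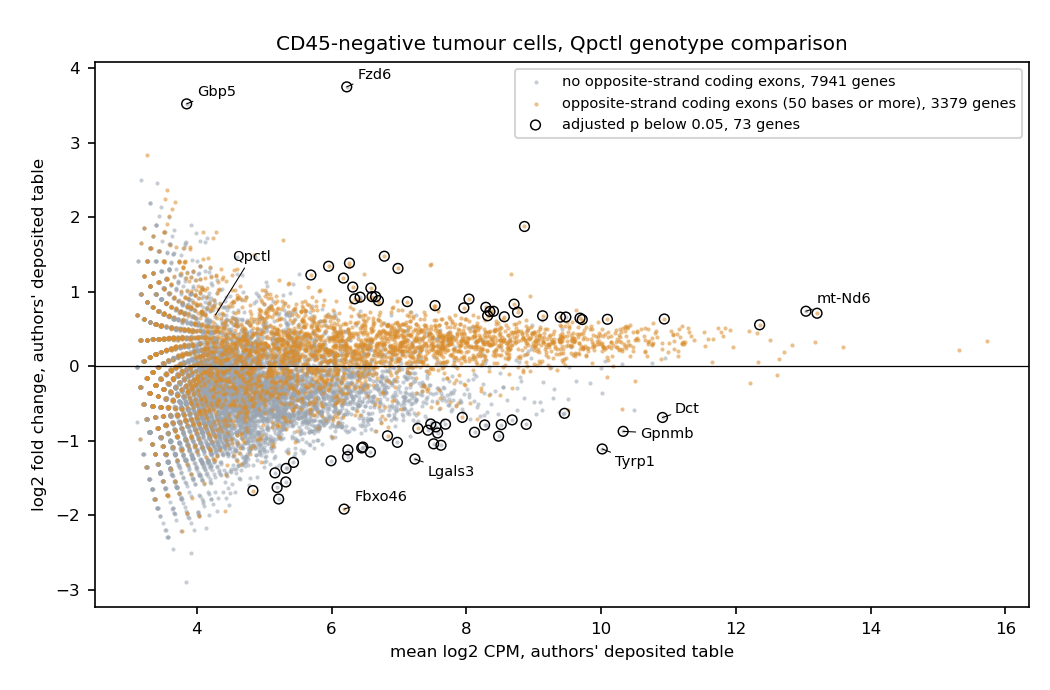
Log2 fold change (vertical axis) against mean log2 CPM (horizontal axis) for the genes of the authors' deposited table, with genes that share at least 50 exonic bases with an opposite-strand coding gene in orange, the others in grey, and the 73 called genes ringed. The 3379 orange genes have a median fold change of 0.25 and the 7941 grey genes have -0.31.

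The largest positive fold change of the authors' deposited table was that of Fzd6, at 3.75 with an adjusted p of 3.75e-12. Fzd6 encodes a Frizzled receptor for Wnt ligands and lies on chromosome 15 (39006034 to 39038188, plus strand). Gbp5, an interferon-inducible guanylate-binding protein gene on chromosome 3 (142493978 to 142522344), followed in the authors' deposited table with 3.52 and an adjusted p of 0.017, at a low mean log2 CPM of 3.85. Neither gene has opposite-strand coding exons. The other 8 positive genes named by the rule share between 116 and 1855 exonic bases with an opposite-strand coding gene. Mterf4, which encodes a mitochondrial ribosome assembly factor, had 1.47 in the authors' deposited table (adjusted p = 0.017) and overlaps Sned1. Mlst8, a subunit of both mTOR complexes, had 1.38 in the authors' deposited table (adjusted p = 0.00184) and overlaps Bricd5. Malsu1 had 1.31 in the authors' deposited table (adjusted p = 5.7e-04) and overlaps Igf2bp3. Art3 had 1.22 in the authors' deposited table (adjusted p = 0.0436) and overlaps Cxcl10, an interferon-inducible chemokine gene. The antisense gene Galnt6os had 1.34, and Traf3ip3, Acvr2a and Teddm2 had 0.90, 0.86 and 0.78 in the authors' deposited table.

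Among the negative calls of the authors' deposited table, Fbxo46 had the lowest fold change, -1.92 with an adjusted p of 1.47e-05. Fbxo46 encodes an F-box protein and is the neighbour of Qpctl on chromosome 7 (19119859 to 19140172, plus strand). The 3′ ends of both genes meet tail to tail and share 471 bases (19139702 to 19140172), which lie in annotated untranslated sequence of each. St3gal1, a sialyltransferase gene, had -1.79 in the authors' deposited table (adjusted p = 0.00686). Soat1, which encodes a cholesterol-esterifying enzyme, had -1.63 in the authors' deposited table (adjusted p = 0.0349). The proteasome subunit genes Psmb4 and Psmd8 had -1.56 and -1.27 in the authors' deposited table, each with an adjusted p of 0.017. Lgals3, the galectin-3 gene, had -1.25 in the authors' deposited table (adjusted p = 0.00184). The thioredoxin-like gene Txnl1 had -1.67, Luzp1 -1.43 and the mitochondrial 12S ribosomal RNA mt-Rnr1 -1.37 in the authors' deposited table, all with adjusted p between 0.0349 and 0.0365. Of these negative genes, Fbxo46 and Txnl1 have opposite-strand coding exons.

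**Figure D2:**
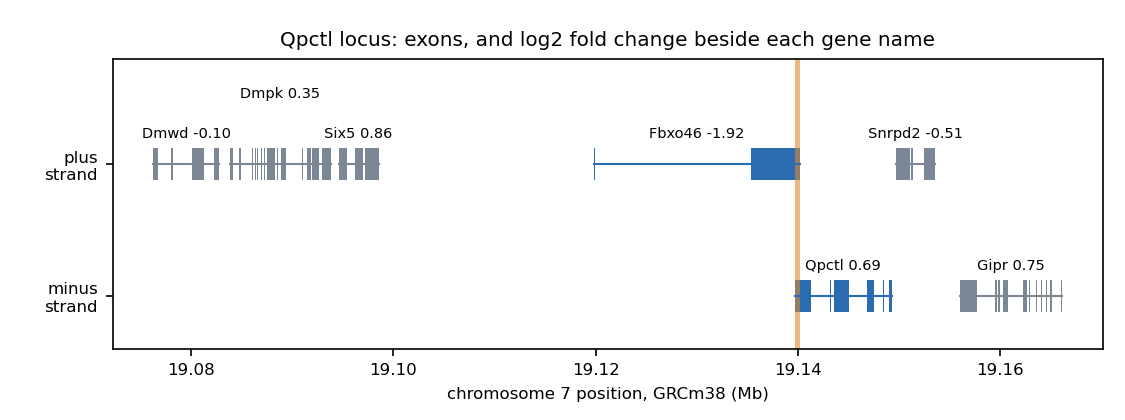
Exons (boxes) of Qpctl, Fbxo46 and neighbouring genes on chromosome 7 (horizontal axis, position in Mb, GRCm38), with the plus strand above and the minus strand below and the log2 fold change of the authors' deposited table beside each name. The orange band is the 471 bases shared by Fbxo46 (-1.92) and Qpctl (0.69).

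Of the 50 gene lists fixed before the data were examined, 27 had at least 5 members in the table and were tested with limma's camera, at a preset correlation of 0.01. Camera called 7 lists, all on the negative side. Members with opposite-strand coding exons numbered 2 of 22 for melanoma identity, 2 of 27 for hypoxia and glycolysis, 8 of 30 for oxidative phosphorylation, 5 of 32 for ribosomal proteins, 5 of 25 for MYC targets, 2 of 23 for cholesterol synthesis and 2 of 20 for heat shock. Melanoma and melanocyte identity genes had a median log2 fold change of -0.62 over the authors' deposited table, which is -0.48 relative to the median of all genes (adjusted p = 4.25e-09). Of its 22 members, 21 were negative in the authors' deposited table, 4 of them called, or 11 when adjusted over the list alone. The pigment enzyme gene Tyrp1 had -1.11 (adjusted p = 5.7e-04), Gpnmb -0.88, the receptor gene Met -0.94 and the pigment enzyme gene Dct -0.69 in the authors' deposited table. Genes of hypoxia and glycolysis had a median of -0.52 over the authors' deposited table, with 23 of 27 members negative and 4 called, or 15 when adjusted over the list alone (camera, adjusted p = 3.42e-08). Bnip3, a hypoxia-induced mitophagy receptor gene, had -1.22 in the authors' deposited table, and the glycolytic genes Pgk1, Ldha and Gpi1 had -0.79, -0.78 and -0.72. An antisense gene opposite Bnip3 had -0.13 (adjusted p = 0.725) in the authors' deposited table. The mean log2 CPM of that antisense gene was 12.62, against 6.24 for Bnip3.

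Nuclear genes of oxidative phosphorylation had the lowest median of the called lists over the authors' deposited table, -0.68, with 28 of 30 members negative and 2 called, or 13 when adjusted over the list alone (camera, adjusted p = 1.76e-08). The respiratory chain gene Cox7b had -1.10 and the ATP synthase gene Atp5a1, which overlaps Haus1, had -0.84 in the authors' deposited table, with adjusted p of 0.0212 and 0.0369. Uqcrc2 (-1.17, adjusted p = 0.0774, overlapping Pdzd9) and Atp5b (-0.61, adjusted p = 0.0928) were not called in the authors' deposited table. Ribosomal protein genes had a median of -0.38 over the authors' deposited table, with 31 of 32 members negative (camera, adjusted p = 2.18e-07). Of the ribosomal members Rps3 (-0.78) was called in the authors' deposited table, or 3 members when adjusted over the list alone, and Rpl37 (-0.71), Rplp0 (-0.58) and Rps4x (-0.63) were not. MYC targets and ribosome biogenesis genes had a median of -0.45 over the authors' deposited table, with 21 of 25 members negative (camera, adjusted p = 8.04e-04). Ldha is also a member of that list and was its only call in the authors' deposited table, with 3 calls when adjusted over the list alone. Hspd1 (-0.72, overlapping Hspe1), Npm1 (-0.48) and Dkc1 (-1.10) were not called in the authors' deposited table.

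Cholesterol synthesis genes had a median of -0.62 over the authors' deposited table, with 21 of 23 members negative and 0 called, or 2 when adjusted over the list alone (camera, adjusted p = 0.00322). Among its members, Hmgcs1 had -0.97, Msmo1 -1.18 and Insig1 -0.62 in the authors' deposited table, with adjusted p between 0.112 and 0.275. Heat shock and tissue dissociation genes had a median of -0.45 over the authors' deposited table, with 16 of 20 members negative and 0 called, or 3 when adjusted over the list alone (camera, adjusted p = 0.0499). The chaperone genes Hsp90aa1 and Hspa8 had -0.62 and -0.60 in the authors' deposited table, Atf3 had -1.46 and Fos -0.60. Among genes without opposite-strand coding exons, whose own median was -0.31 over the authors' deposited table, camera kept the calls of melanoma, hypoxia and glycolysis, oxidative phosphorylation and ribosomal proteins. The adjusted p there were 0.0565 for cholesterol synthesis, 0.0625 for MYC targets and 0.273 for heat shock. Against random coding genes of that class with matched mean log2 CPM, the list medians lay at percentiles of 5.92 for ribosomal proteins, 11.99 for heat shock and 16.18 for MYC targets, and at 0.5 or lower for the other 4 lists. With the log2 fold change as the statistic, the adjusted p were 0.0962 for hypoxia and glycolysis, 0.186 for ribosomal proteins, 0.193 for MYC targets and 0.306 for heat shock. The heat shock list also lost its call at a correlation of 0.05 (adjusted p = 0.201), on ranks (0.0946) and among genes with a mean log2 CPM of at least 4 (0.0538).

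**Figure D3:**
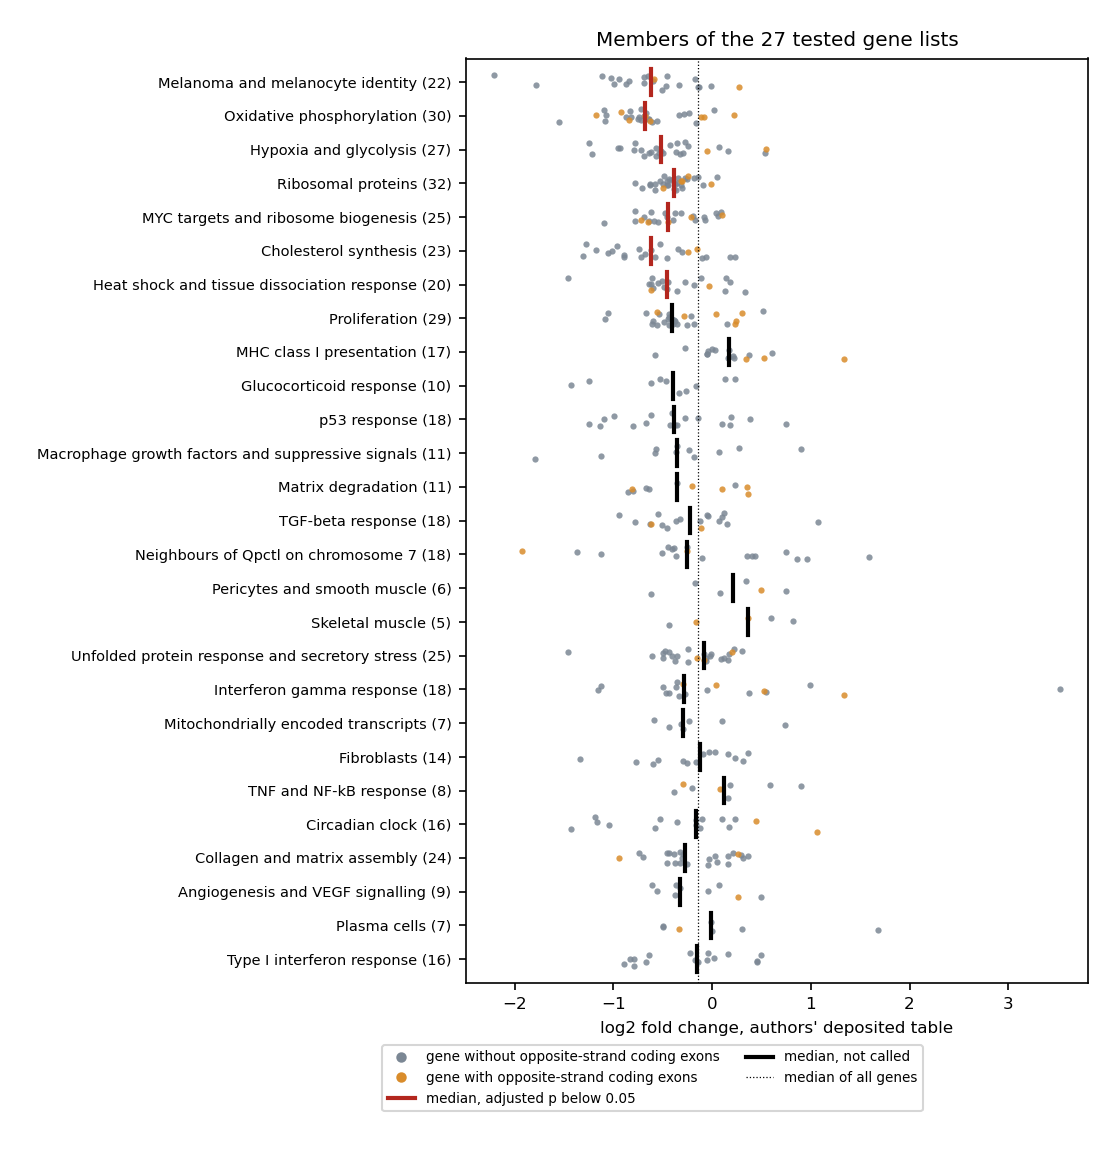
Log2 fold change in the authors' deposited table (horizontal axis) of the members of the 27 tested lists, 1 point per gene, with the number of members in brackets, genes with opposite-strand coding exons in orange and the list median as a bar, red where camera gave an adjusted p below 0.05. The 7 red bars lie between -0.68 and -0.38, left of the dotted median of all genes at -0.14.

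Immune response lists were not called. MHC class I presentation genes had a median of 0.17 over the authors' deposited table, with 11 of 17 members positive and 0 called, or 1 when adjusted over the list alone (camera, adjusted p = 0.19). The immunoproteasome gene Psmb9, which overlaps Tap1 on the opposite strand, had 1.34 and an adjusted p of 0.0549 in the authors' deposited table. B2m had -0.58, Erap1, which overlaps Cast, 0.34 and Calr 0.22 in the authors' deposited table, with adjusted p between 0.246 and 0.541. For interferon gamma response genes the median over the authors' deposited table was -0.29, while the camera statistic was on the positive side (adjusted p = 0.545), so the signs differed. Of its 18 members, Gbp5 was called in the authors' deposited table, or 2 members when adjusted over the list alone, whereas Cd274 (-1.12) was not. Type I interferon response genes had a median of -0.15 over the authors' deposited table and a camera adjusted p of 0.856, with Bst2, Ifih1 and Isg15 at -0.64, -0.79 and -0.83 and Ifi35 at 0.46. TGF-beta response genes had a median of -0.23 over the authors' deposited table and a camera adjusted p of 0.373, with Ccn1 at -0.63, Fn1 at -0.46, Thbs1 at -0.94 and Ccn2 at -0.54.

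No tested list of markers of other cell types was called. Fibroblast genes had a median of -0.13 over the authors' deposited table (camera, adjusted p = 0.601), with Sparc at -0.60, Postn at -1.34, Col6a3 at -0.77 and Fbln1 at -0.55. Collagen and matrix assembly genes had a median of -0.28 over the authors' deposited table and a camera adjusted p of 0.601. Pericyte and smooth muscle genes had a median of 0.21 over the authors' deposited table and a camera adjusted p of 0.497. Of the leukocyte list, which the CD45 gate should deplete, 3 members were among the genes of the authors' deposited table, Ptpn6 (-0.60), Arhgdib (-0.25, overlapping Pde6h) and Lcp1 (-0.53), too few for a list test. Blood endothelium had 2 members in the authors' deposited table. The erythroid list had 3, of which the transferrin receptor gene Tfrc was called in the authors' deposited table (-1.15, adjusted p = 0.0124). Proliferation genes had a median of -0.40 over the authors' deposited table, with 23 of 29 members negative and 0 called in either adjustment (camera, adjusted p = 0.0728), and Mki67 had -0.49. Camera called that list on ranks (adjusted p = 0.0322) and at a correlation of 0 (adjusted p = 0.0315). For plasma cell genes the median over the authors' deposited table was -0.01 while the camera statistic was on the positive side (adjusted p = 0.719), so the signs differed. The remaining tested lists, among them p53 response, unfolded protein response, circadian clock and mitochondrially encoded transcripts, had camera adjusted p between 0.231 and 0.719.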

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

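All alternatives here were chosen after seeing the data. The alternatives named beforehand for the counts (other size factors, DESeq2, limma-voom, other filters, all 48 libraries in 1 fit, leaving out each replicate, covariates, an estimated correlation and other splits of the samples) were not run, because the count columns carry no genotype. No paired analysis was possible because the columns carry no replicate number that matches a sample title. The count of 73 called genes (37 positive, 36 negative) in the authors' deposited table became 14 (7 and 7) at an adjusted p below 0.01, 292 (145 and 147) below 0.1 and 10 (5 and 5) with Bonferroni adjustment, by construction of the thresholds. With adjustment over genes at a mean log2 CPM of at least 4 it became 163 (79 and 84), which include 72 of the 73. Without genes that have opposite-strand coding exons it was 34 (4 positive and 30 negative), and with protein-coding genes of that class alone 33 (4 and 29). Most of the loss on the positive side is the 32 positive calls removed with the class, and of the 36 calls outside it 34 were kept. Camera called 7 lists, and 3 with the log2 fold change as the statistic and 4 without opposite-strand genes; the cause was not tested. It called 6 at a correlation of 0.05, 8 at 0, 7 on ranks and 6 at a mean log2 CPM of at least 4. Proliferation was gained at 0 (adjusted p = 0.0315) and on ranks (0.0322), where heat shock was lost (0.0946). Melanoma identity and oxidative phosphorylation were called in 6 of 6 alternatives, with adjusted p up to 0.00153 and 0.00128, and heat shock in 1 of 6, with adjusted p from 0.0259 to 0.306. Over all lists and alternatives, 146 of the outcomes stayed on their side of the threshold, 10 lost a call and 2 gained one. For named genes the counts were 203, 45 and 10. With minimums of 1 and 200 shared bases the opposite-strand class had medians of 0.24 and 0.28, against -0.31 and -0.26 outside it. Depth per library was not analysed here, so its effect on uncalled genes is open.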

Other observations

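Interferon and antigen presentation genes appear in the table a second time, as the coding partners of overlapping genes. The following test, and the genes named with it, were chosen after the values were seen. Among the 3379 genes of the authors' deposited table with opposite-strand coding exons, 13 have a partner in the interferon gamma or MHC class I lists, and 13 of 13 had a positive fold change. Their median was 0.95 against 0.25 for all genes of the class in the authors' deposited table (camera, adjusted p = 2.3e-05, in a family of 13 lists plus this union). By list, 8 of 8 partners of interferon gamma genes (median 1.23, adjusted p = 6.8e-04) and 9 of 9 partners of MHC class I genes (median 0.95, adjusted p = 9e-04) were positive in the authors' deposited table. These sets share 4 genes, and 2 of the 13, Psmb9 and Tap1, are themselves members of the lists. Positive signs were common in the class, with 559 of 582 genes positive at a mean log2 CPM of at least 8. Partners of collagen and matrix genes were also positive in 6 of 6 cases (median 0.43, camera, adjusted p = 0.98). The sign counts alone therefore do not set the 13 genes apart. In the authors' deposited table Gm20496, opposite the immunoproteasome gene Psmb8, had 1.87 (adjusted p = 0.0131), Art3, opposite Cxcl10, had 1.22, and Gm15821, opposite the peptide transporter gene Tap2, had 1.24 (adjusted p = 0.0516). Gm19412, opposite Tapbp, had 0.95, Gm17334, opposite Irf1, had 0.78 and Gm36043, opposite Cd274, had 0.66 in the authors' deposited table. The 13 values of the authors' deposited table ran from 0.42 (opposite H2-Q4) to 2.36 (Dexi, opposite Ciita, at a mean log2 CPM of 3.56), and 2 were called. A hypothesis is that these genes carry reads of the partner, in which case interferon gamma and MHC class I transcripts may differ between the genotypes on the positive side, although the lists' own members gave no list call. Counting the reads again with the strand setting reversed would decide it, which was not analysed here. Of the 13 genes, 7 lie on chromosome 17, where overlapping genes have a higher median in the authors' deposited table (0.44). Set against overlapping genes of matched mean log2 CPM from the same part of the genome, the 7 had a median of 0.95 against 0.47, and the 6 on other chromosomes 1.002 against 0.25 in the authors' deposited table. Both medians lay above the central 95% of sets, whose upper ends were 0.63 and 0.50. The genes in the MHC are neighbours and not independent, and camera used a preset correlation.

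The most abundant genes of the authors' deposited table were mostly overlapping or antisense genes, and 3 explanations were weighed. The tests on mt-Nd6 and on contained genes were chosen after the pattern was seen. For natural antisense transcription, the form with antisense genes below their partners is argued against. Of 771 antisense genes, 617 (80.03%, 95% exact interval 77.03 to 82.79) lay above their coding partner in mean log2 CPM. Antisense transcription above the partner's level would give the same values and was not tested. Counting without strand is argued against by genes that lie with at least 90% of their exonic bases inside exons of an opposite-strand coding gene, of which 118 of 158 (74.68%, 67.16 to 81.26) lay above that gene, although both would receive the same reads. A first test of that explanation, the percentile of ribosomal protein genes without the overlap (median 90.71 against a bound of 90 set for it), had gone the other way by a small margin and was replaced. Reads assigned to the strand opposite to the transcript would raise antisense and contained genes above their partners, as seen. They would also raise mt-Nd6, the light-strand coding gene of the mitochondrion, which lay 4.098 log2 units above the median of 6 heavy-strand coding genes. These values go with that explanation, which stays open because the reads were not counted again with the strand setting reversed. If that is so, most genes would carry few reads of their own transcripts, and the fold changes and list medians given for them may not describe those transcripts. No other biological explanation was tested.

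The negative lists and genes were set against the shift of their own class, genes without opposite-strand coding exons. These list tests were written down before their outcome was seen, and the finer matching and the test on opposite-strand genes were added after. If list members vary independently, a uniform shift is argued against for melanoma identity (percentile 0 of 10000 matched sets), oxidative phosphorylation (0.02), hypoxia and glycolysis (0.16) and cholesterol synthesis (0.5). It may account for the medians of ribosomal proteins (5.92), heat shock (11.99) and MYC targets (16.18). The matched sets draw genes independently, so their spread does not cover lists whose members vary together. For ribosomal proteins camera within the class still gave an adjusted p of 5.85e-06, and for cholesterol synthesis 0.0565, so both measures differ there. The matched sets used each gene's own mean log2 CPM, which need not be its transcript level if reads were counted on the opposite strand. The percentiles therefore do not separate a change of the transcripts from a difference in strand specificity between the groups. Under the open strand explanation the transcripts would be read from their opposite-strand genes, whose medians in the authors' deposited table were 0.23 for oxidative phosphorylation (camera, adjusted p = 0.98), 0.32 for cholesterol synthesis (0.98) and -0.08 for hypoxia and glycolysis (0.21), against 0.25 for the class. A negative shift of the transcripts of these 3 lists is therefore not shown, and melanoma identity, with 3 such genes at 0.50, 0.36 and 0.28 in the authors' deposited table, had too few for a list test. The 9 genes opposite to called negative genes other than Fbxo46 had a median of 0.10 in the authors' deposited table, at percentile 1.48 of matched genes with the overlap (median 0.33), with 3 of 9 negative and 0 called. That is low for the class yet positive, and far from the median of -0.90 of the called genes opposite them in the authors' deposited table. Of the 9, 6 had a higher mean log2 CPM than the called gene opposite, and the median of those 6 alone was not computed. The negative genes Haus1 (-0.28) and Nsmaf (-0.51) lay below theirs. The other negative gene, Gm45507 opposite Bnip3, had -0.13 and lay above it (12.62 against 6.24). A change of the transcripts themselves toward the negative side of their class stays open (1.48). A difference in strand specificity between the groups, which could also part the signs of genes with and without the overlap, was not tested.

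For Fbxo46 both tests were chosen after its value was seen. A shift of the whole neighbourhood of Qpctl as large as that of Fbxo46 is argued against by the other 17 neighbours. Their median was -0.25 in the authors' deposited table, at percentile 20.41 of matched sets, with 0 called. The matched sets had a median of -0.11, and with matching in bins the percentile was 37.38. Most of the neighbours have no opposite-strand coding exons, a class with a median of -0.31 in the authors' deposited table. A smaller shift, or one of mixed sign, is not excluded by so few genes, whose values ran from -1.37 to 1.59 in the authors' deposited table. Reads of Qpctl counted for Fbxo46 stay open as a candidate explanation. The 471 exonic bases shared on opposite strands prompted it and so do not test it. If it held and the knockout lowered Qpctl transcripts, negative would mean lower in the knockout. Neither condition was tested, so the direction of the subtraction stays unsettled. A change of Fbxo46 itself next to the altered allele is open and untested.

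Chromosomes 17 and X were picked after the chromosome medians of the authors' deposited table had been seen, as the highest (0.11) and the lowest (-0.40) of 20. The test by class was written down before its outcome was seen, but it uses the same genes and in part restates those medians. Genes of chromosome 17 lay 0.21 above matched sets with opposite-strand coding exons (181 genes) and 0.22 above them without (391 genes), each above all 10000 sets. In windows of 20 Mb the median relative to the class ran from 0.10 to 0.25, so it was not limited to the window with the MHC. A change that follows the chromosome, such as a copy number difference between the tumour lines, is a hypothesis these values leave open (smaller difference 0.21). DNA copy number of both tumour lines would decide it, which was not analysed here, and random sets treat neighbouring genes as independent. Of 20 chromosomes, 3 lay outside the central 95% of sets in the same direction in both classes. These were 17 and 6 above and 2 below, the last at the bound in genes without the overlap (percentile 2.49). Others lay outside in a single class. Among them, chromosome 3 without the overlap and 16 with it were at percentile 0, and 5 with it at 100. An extreme percentile in a single class was therefore not particular to chromosome 17. For chromosome X the differences were -0.1212 and -0.14, and the former, from 39 genes, lay inside the central range close to its bound of 2.5, at percentile 3.69, or 2.55 with matching in bins. With so few genes that value excludes nothing, and a change that follows chromosome X stays open.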
